A study of Mus musculus with 8 samples.

How the data were processed

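Expression was measured on Illumina bead arrays in MLL-AF9 leukaemia stem cells sorted from mouse bone marrow, with total RNA isolated by Trizol and labelled with biotin by the standard Illumina protocol, per the labels. Arrays were assigned to the Luc control (3 arrays), Itgb3-17 knockdown (3 arrays) and Itgb3-20 knockdown (2 arrays) groups from their titles. The signal of each probe is an average bead intensity on a linear scale that was not normalized, per the file headers as deposited. The detection p-value beside each signal was deposited by the authors, with its method not given in the sources used here. A further table deposited by the authors holds processed log2 values of the same arrays. Within each array these values had the same rank order as the signals (Spearman 1) and each column had a median of 6.61, which fits log2 values after quantile normalization with no background subtraction. The method, the centring and any offset of that table are not stated and stay unknown, and it was used only as an alternative.

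Signals were processed with limma 3.58.1 in R 4.3.3. Background was corrected by normexp with negative controls inferred from the detection p-values (neqc), with an offset of 16, followed by quantile normalization and log2. Probes with a detection p under 0.05 on at least 2 arrays were tested, 13315 of 45281. Gene symbols came from an annotation table of the array. Of the probes with values, 34885 had 1 symbol, 18 had several and were not named, and 10378 were unnamed here. Symbols were checked through 34807 gene identifiers in a RefSeq table of the GRCm38.p6 assembly, used for names only, and 0 symbols changed. The tested probes covered 8189 gene symbols. Where a gene had several tested probes, the probe of highest mean over the 8 arrays stood for it. Median signals lay between 91.2 and 102 on the 8 arrays, and no arrays held identical values.

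A limma model with the 3 groups (lmFit and eBayes, two-sided) was fitted to all 8 arrays, so that the groups shared an estimate of the spread. Knockdown minus control was the mean of both hairpin groups minus the Luc control group, and each hairpin minus control and Itgb3-20 minus Itgb3-17 were taken from the same fit. Adjusted p-values are by Benjamini-Hochberg over the tested probes, with 0.05 as the threshold for a call. The median standard error of knockdown minus control was 0.154 on the log2 scale. Where a gene was below background on every array of a group, the fold is a bound. It sets the mean of the brighter group against the dimmer group's mean of, per array, the higher of the lowest signal above background and the gene's own signal. Because both hairpins share the controls, 100 simulations drew 8 arrays with no difference between the groups, from each probe's mean and moderated spread, and set both simulated hairpin groups against the same simulated controls.

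The design, the alternatives other than the averaged probes below, the 30 gene lists and the rule for named genes were fixed before the data were examined. The lists were integrin subunits, integrin signalling, MLL-AF9 targets, haematopoietic stem cell genes, monocyte and macrophage genes, granulocyte genes, G1/S and G2/M cell cycle genes, p53 targets and cell cycle inhibitors, Myc targets and ribosome biogenesis, interferon response, NF-kB and inflammatory genes, immediate early genes, hypoxia and glycolysis, oxidative phosphorylation, unfolded protein and integrated stress response, cholesterol synthesis, ribosomal proteins, heat shock and handling stress, sort gate markers, Y-linked and X-inactivation genes, and markers of erythroid cells, megakaryocytes and platelets, B cells, T cells, NK cells, mast cells and basophils, eosinophils, dendritic cells and antigen presentation, and stromal and endothelial cells. Of their 817 genes, 812 matched a current symbol. The 20 lists with at least 5 tested genes were tested by camera with a preset correlation of 0.01, and counts were also adjusted over each list alone. Of the camera calls for knockdown against control, 1 list higher and 1 lower, 0 held with an estimated correlation. Fry was run as an alternative; it tests whether the genes of a list move on balance in a common direction and does not compare the list with other genes.

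Named genes were Itgb3, the 12 genes of largest rise and the 12 of largest fall among called probes whose knockdown arrays all lay on the same side of all controls, up to 4 members of lowest p in each list, the 5 of largest change with each hairpin and in the hairpin difference, and the genes of the sort gate and Syk whatever their value. Any other gene is said to have been singled out after its values were seen. Of the 126 genes so selected for knockdown against control, 80 are described. Which of them to describe was decided after their values were seen, and genes whose call was lost when an array was left out were often passed over. By this choice the genes described keep their calls without an array more often than those selected. Counts of stability are therefore given over all 126.

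The fit was tested on simulated data with the 13315 probes of knockdown against control, in 10 runs with 200 changed probes each. It recovered 52.5% of probes changed 1.5-fold, 99.9% of those changed 2-fold and 100% of those changed 3-fold, with 6.4% false calls. Lists of 20 genes shifted by 0.3 (log2) were called in 100% of cases and unshifted lists in 2%. The simulated probes were drawn independently of each other, so these rates need not hold for lists of correlated genes. In the data 2233 probes were called, far more than the 200 changed per run, so the recovery rates may differ there. Alternatives were no background correction, the authors' processed values, median scaling in place of quantile normalization, no filter and a stricter filter (detection p under 0.01 on all arrays of at least 1 group), trend and robust moderation, array weights, leaving out each array, a fit of the knockdown arrays as a single group, only the groups compared, the replicate number as a block, a 1.5-fold size threshold, and for lists an estimated correlation, fry and the mean of all probes of a gene. Averaging the probes of a gene before the fit was added after seeing the data.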

Results

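The arrays measured gene expression in mouse leukaemia stem cells driven by the MLL-AF9 fusion oncogene. The cells had been sorted from the bone marrow of mice carrying a leukaemia passed through a quaternary transplant, as dsRed-positive cells with low Hoechst stain, high c-kit, CD34 and high Fc gamma receptor II. They carried either a control hairpin against luciferase (Luc control, 3 arrays) or a hairpin against Itgb3, the gene of the integrin beta 3 subunit (Itgb3-17 knockdown, 3 arrays, and Itgb3-20 knockdown, 2 arrays). The series asked how knockdown of Itgb3 changes expression in primary leukaemia cells. Each array reported 45281 probes, of which 9262 to 11856 (20.5% to 26.2%) were above background, and the number of arrays limits the precision. The labels do not say whether arrays of a group came from separate mice, so the p-values measure the spread between these samples, which may be technical. On the 8 arrays together the leading principal component held 42.1% of the variance, with the controls at -30.2, -27.1 and -19.8 and every knockdown array between 8.01 and 26.9.

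The knocked-down gene was read first. Itgb3 had 1 probe, and it was above background on 0 of the 8 arrays, with detection p-values from 0.324 to 0.912. Its log2 level was 4.28 in the Luc control and Itgb3-17 groups and 4.22 in the Itgb3-20 group. The knockdown minus control difference was -0.03 ± 0.0587 (SE, limma unadjusted p = 0.624). Because the probe did not rise above background in the control cells, neither the knockdown nor the sample labels could be checked from it. Syk and Cd34 were not among the tested probes.

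Knockdown against control compared the mean of both hairpins with the controls. Lyz1, a lysozyme of myeloid cells, rose by 1.58 ± 0.145 on the log2 scale (SE; adjusted p = 3.83e-05), from 7.94 ± 0.07 (SD, n = 3) in the controls to 9.43 ± 0.54 (SD, n = 5) in the knockdown arrays. The knockdown level is a mean over arrays, while the change weights both hairpins equally. Lyz1 lay at 9.05 with Itgb3-17 and 9.99 with Itgb3-20, a called difference (0.94, adjusted p = 0.0302). That call ended under median scaling (adjusted p = 0.337), with no filter (0.0843) and without Itgb3-17 replicate 1 (0.0519), 2 (0.133) or 3 (0.103). Without Itgb3-20 replicate 4, which left 1 array of that hairpin, the difference was 0.87. Hipk2, a nuclear serine/threonine kinase, fell by 1.52 ± 0.144 (SE; adjusted p = 4.21e-05), from 8.32 ± 0.18 (SD, n = 3) to 6.80 ± 0.12 (SD, n = 5). Among the genes selected, the largest fall was that of Eef2, the elongation factor that moves the ribosome along the message, at -2.20 ± 0.329 (SE; adjusted p = 0.000694), with a wide spread over the knockdown arrays (6.70 ± 1.04, SD). Ltf, the lactoferrin of secondary granules, was not above background in the control arrays and was at least 1.88-fold higher in the knockdown arrays (adjusted p = 0.000363).

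The other rises among the 12 largest were those of Erich5 (1.63), Srr (1.30), Preb (1.25), Gstm1 (1.24), Rin3 (1.22), S100a13 (1.21), Mgmt (1.17), Tcirg1 (1.14), Foxp3 (1.13) and Camp (1.13), with adjusted p from 0.000174 to 0.00226. They include Gstm1, a glutathione transferase, Mgmt, a DNA repair methyltransferase, Tcirg1, a subunit of the vacuolar proton pump, and Foxp3, the transcription factor of regulatory T cells. The other falls among the 12 largest were those of Erg28 (-1.60), Serp1 (-1.50), App (-1.48), Atp2a2 (-1.46), Timm17a (-1.44), Syngr2 (-1.39), Rbbp7 (-1.36), Rpl30 (-1.34), Xxylt1 (-1.33) and Tex2 (-1.31), with adjusted p from 5.15e-05 to 0.00144. Among these Serp1 and Atp2a2 act in the endoplasmic reticulum, the latter as its calcium pump, and Timm17a belongs to the mitochondrial import machinery. For all 24 genes the 5 knockdown arrays lay on the same side of the 3 control arrays, as the selection required.

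With limma, 1189 of 13315 tested probes were higher and 1044 lower (adjusted p under 0.05, 16.8% together). By the probe that stood for each gene, 775 gene symbols were higher and 676 lower. Of the called probes, 69 were at least 2-fold higher and 125 at least 2-fold lower. All 5 knockdown arrays lay above all 3 controls for 1527 probes and below for 1181, 20.3% of those tested against 3.57% by chance. The balance of rises and falls depended on the scaling. When arrays were only scaled to a common median, 1327 tested probes were higher and 79 lower (94.4% higher against 53.2%). That median was taken over all 45281 probes, of which only 20.5% to 26.2% on an array were above background. The median change of the tested probes moved to 0.149. Of the genes selected by the rule for named genes, 16 of the 42 called falls and all 46 called rises were called, among them all of the 24 above. The counts were 748 higher without Luc control replicate 1, and 688 higher and 679 lower without Luc control replicate 2; without a filter on dim probes, 649 were lower and Camp lost its call (adjusted p = 0.0512).

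**Figure D1:**
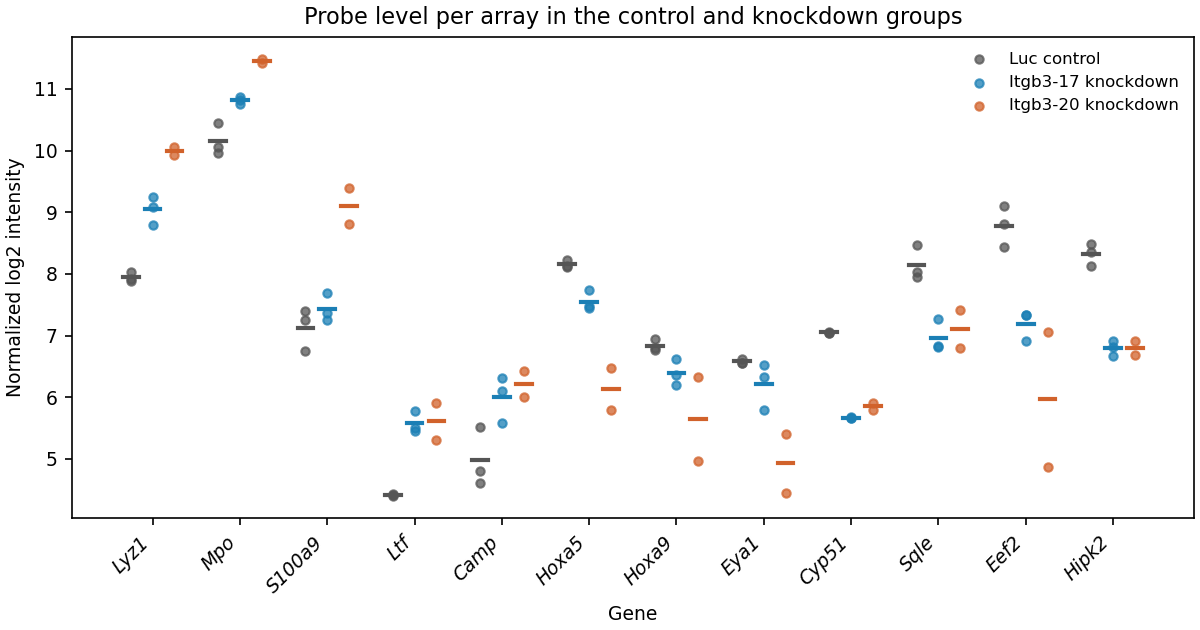
Normalized log2 intensity of 12 genes on each of the 8 arrays, with 1 point per array and a bar at the group mean. Lyz1 lay near 7.94 in the controls and 9.99 with Itgb3-20, while Cyp51 and Hipk2 were lower on every knockdown array than on every control array.

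Probes of a single gene did not always move together. Of 4082 pairs of tested probes for 2331 genes, 57.4% changed in the same direction between knockdown and control, and their log2 fold changes correlated at 0.219 (across probe pairs, which are not independent replicates). Both probes were called in 257 pairs, and in 62 of these (24.1%, 46 genes) they were called in opposite directions. Actb, the cytoskeletal actin and a gene singled out after its values were seen, had 5 called probes at -0.80, 1.03, -1.53, 1.91 and 1.71. The first 3 were above background on every array. Those at 1.91 and 1.71 were above background on 1 and 0 of the 3 controls, so the size of the last is uncertain. Their SD over the 2 Itgb3-20 arrays was 2.71 and 2.75. Among the genes named here for a called change between knockdown and control, App, Birc5, Eef2, Hoxa9, Mgmt, Mpo, Pfkp, Preb, Rbbp7, Sqle, Srr, Syngr2 and Tcirg1 had another probe called in the same direction, and Rpl23 had one called in the opposite direction. Of the 73 such genes, 36 had another tested probe, and in 10 of these an uncalled probe had the opposite sign. Those of the 36 not listed above, among them Hipk2 and Erg28, had no other probe called. The other probes of Hipk2 were at -0.04 and -0.38 (limma adjusted p = 0.885 and 0.0665). Those of Erg28 were at 0.21 and 0.13 (0.397 and 0.635).

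Genes of the granulocyte lineage were among the rises. Of 29 tested granulocyte genes, 10 rose and 0 fell over all probes tested, and 10 rose and 1 fell adjusted over the list alone (13 and 1 at an unadjusted p under 0.05). They included Ltf, Mpo, the myeloperoxidase of primary granules (0.99 ± 0.147, adjusted p = 0.000694), S100a9, a calprotectin subunit (1.14 ± 0.183, adjusted p = 0.000968; 0.30 and 0.366 with Itgb3-17, 1.97 and 0.000274 with Itgb3-20), and Camp, the cathelicidin of secondary granules (1.13 ± 0.211, adjusted p = 0.00226). The list shifted up by camera (median 0.199, adjusted p = 0.0143, and 0.369 with an estimated correlation). Under median scaling its shift relative to all tested probes was 0.485. By fry its adjusted p was 0.00799 (upward). Its adjusted p was 0.108 without Itgb3-20 replicate 5 and 0.0859 in a fit of the knockdown arrays as a single group, where the adjusted p of S100a9 was 0.093. Of 26 monocyte and macrophage genes, 3 rose and 0 fell (2 and 0 adjusted over the list alone, 7 and 0 at an unadjusted p under 0.05): Lyz1, Pld4, a lysosomal nuclease (0.76 ± 0.162, adjusted p = 0.00518), and Lyz2, the macrophage lysozyme (0.46 ± 0.15, adjusted p = 0.0458). Lyz2 lay at -0.11 with Itgb3-17 (adjusted p = 0.72) and at 1.03 with Itgb3-20 (0.00351), on opposite sides of the control except under median scaling (0.34 with Itgb3-17). The difference was called (1.14, adjusted p = 0.0111; lost without Itgb3-17 replicate 2 at 1.07 and 0.0978 or replicate 3 at 1.11 and 0.0588, under median scaling and with no filter). The call of Lyz2 for both hairpins together was lost when any of the 8 arrays was left out (adjusted p from 0.0539 to 0.193, log2 change from 0.33 to 0.54), and with no filter on dim probes (0.0929), array weights (0.0505) or a single knockdown group (0.442). The monocyte list had a median of 0.0297 (camera adjusted p = 0.488; fry adjusted p = 0.00511, upward).

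Targets of MLL-AF9 fell or did not pass. Of 20 tested targets, 0 rose and 4 fell, and the same counts held adjusted over the list alone (0 and 6 at an unadjusted p under 0.05). The 4 were Hoxa5 (-1.31 ± 0.163, adjusted p = 0.000323) and Hoxa9 (-0.81 ± 0.228, adjusted p = 0.0222), homeobox genes of the HOXA cluster, Eya1, a transcriptional coactivator (-1.01 ± 0.206, adjusted p = 0.00382), and Cbx5, a heterochromatin protein (-0.79 ± 0.146, adjusted p = 0.00203). Hoxa9 and Eya1 were not called with Itgb3-17 (-0.44, adjusted p = 0.284, and -0.37, 0.319) and were with Itgb3-20 (-1.19, 0.014, and -1.66, 0.00144), where Hoxa9 was at -0.51 (0.248) without replicate 4 and at -1.85 (6.73e-05) without replicate 5, and lost its call under median scaling (-0.92, 0.197) and with no filter (0.159). The hairpins differed for Eya1 (-1.28, adjusted p = 0.0323), a call lost without Luc control replicate 2 (-1.30, 0.0566) or 3 (-1.29, 0.0611), Itgb3-17 replicate 1 (-1.09, 0.148) or 2 (-1.24, 0.183) and Itgb3-20 replicate 4 (-0.81, 0.227), under median scaling and with no filter, and not for Hoxa9 (-0.75, 0.284). The list as a whole did not pass by camera (adjusted p = 0.0655, and 0.369 with an estimated correlation) but did by fry (adjusted p = 0.00799, downward). Its median was -0.153, and under median scaling it was 0.0466, or -0.103 relative to all tested probes. The list passed without Itgb3-17 replicate 2 (adjusted p = 0.0419) or Itgb3-20 replicate 4 (0.0339). Hoxa9 lost its call without Luc control replicate 1 (-0.85, adjusted p = 0.0597), 2 (-0.85, 0.0652) or 3 (-0.76, 0.0825) and without Itgb3-20 replicate 4 (-0.48, 0.0632), and of the 4 genes only Hoxa5 was called under median scaling. Eya1 and Hoxa9 were also lost with no filter on dim probes (adjusted p = 0.0656 and 0.204) and in the fit of the knockdown arrays as a single group (0.0771 and 0.0752). Of 12 haematopoietic stem cell genes, 0 rose and 0 fell, also adjusted over the list alone (limma; 0 and 1 at an unadjusted p under 0.05; camera adjusted p = 0.806). The member of lowest p, Mecom, had a log2 difference of -0.47 ± 0.19 (adjusted p = 0.104) and was called without Luc control replicate 3 (-0.73, adjusted p = 0.0161) and with trend and robust moderation (0.0475). Its level was 4.82 in the controls, 4.32 with Itgb3-17 and 4.39 with Itgb3-20. The Itgb3 probe, below background on every array, lay at 4.28 in the controls, so the size of this fall is uncertain.

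Cholesterol synthesis genes were among the falls. Of 17 tested, 0 rose and 7 fell over all probes, and 1 rose and 7 fell adjusted over the list alone (1 and 7 at an unadjusted p under 0.05). Cyp51, the sterol demethylase, fell by 1.29 ± 0.13 (SE; adjusted p = 5.15e-05), from 7.05 to 5.74 with no overlap between the groups. Sqle, the squalene epoxidase, fell by 1.11 ± 0.182 (SE; adjusted p = 0.00107), Nsdhl, a sterol dehydrogenase, by a log2 difference of -0.77 (adjusted p = 0.00472) and Mvd, the mevalonate diphosphate decarboxylase, of -0.52 (adjusted p = 0.0133; 0.0619 without Luc control replicate 2, at -0.47). The list shifted down by camera (median -0.209, adjusted p = 0.039; with an estimated correlation adjusted p = 0.369). The adjusted p was 0.0916 without Luc control replicate 3, 0.108 without Itgb3-20 replicate 5 (median -0.315) and 0.0594 with the mean of all probes of a gene. By fry the list also passed (adjusted p = 0.000118, downward). Under median scaling the median of the list was 0.0308, or -0.118 relative to all tested probes (camera adjusted p = 0.0475). Of the 4 genes only Cyp51 was called in that setting.

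Cell cycle genes moved both ways. Of 27 G1/S genes, 3 rose and 6 fell, the same adjusted over the list alone. Mcm5, a subunit of the replicative helicase, rose by 0.72 ± 0.14 (SE; adjusted p = 0.00292), and Chaf1b, a chromatin assembly subunit, by 0.70 ± 0.139 (adjusted p = 0.00345), while Gins2, another replication factor, fell by 0.79 ± 0.153 (adjusted p = 0.00295). Of 21 G2/M genes, 0 rose and 4 fell (1 and 4 adjusted over the list alone, 1 and 5 at an unadjusted p under 0.05). The 4 were Ckap2 (-0.98, adjusted p = 0.000912), the mitotic kinase Plk1 (-0.73, adjusted p = 0.00485), Anln (-0.62, adjusted p = 0.00631) and Birc5 (-0.65, adjusted p = 0.00841; -0.57 and 0.0523 without Luc control replicate 2). Of these 4 only Ckap2 was called with both hairpins, and the others with Itgb3-17 and not Itgb3-20. Neither list passed by camera (adjusted p = 0.488 for each), and by fry the G2/M list did (adjusted p = 0.0396, downward). Their medians of -0.13 and -0.0171 turned to 0.122 and 0.24 under median scaling (-0.0276 and 0.0904 relative to all tested probes). Of the 5 falls named only that of Ckap2 was called in that setting. Of 19 p53 targets and cell cycle inhibitors, 3 rose and 2 fell, the same adjusted over the list alone (median 0.0749, camera adjusted p = 0.95). Under median scaling their median was -0.0355 relative to all tested probes.

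Other integrins and their signalling partners were read as well. Of 9 tested integrin subunits, 0 rose and 0 fell, also adjusted over the list alone (limma; 2 and 0 at an unadjusted p under 0.05; camera adjusted p = 0.488; fry adjusted p = 0.0409, upward). Itgb7 was at 0.54 ± 0.193 (adjusted p = 0.0662) and was called without Itgb3-17 replicate 2 (0.66, adjusted p = 0.0352). Of 26 integrin signalling genes, 4 rose and 2 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.833). Rac1, a small GTPase of the cytoskeleton, had the lowest p (-0.79 ± 0.157, adjusted p = 0.00348; 0.0743 under median scaling).

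Markers of the sort and of other cell types were read in the same way. Of the 3 sort gate markers tested, 1 rose and 0 fell (2 and 0 both adjusted over the list alone and at an unadjusted p under 0.05). Fcgr2b, a receptor of the gate, rose by 0.51 ± 0.137 (adjusted p = 0.0181), and its adjusted p was 0.0617 without Luc control replicate 1 (0.50), 0.0548 without replicate 3 (0.49) and 0.0505 without Itgb3-20 replicate 4 (0.48). Fcgr3 was at 0.43 ± 0.156 (adjusted p = 0.0691, called with no background correction at 0.0252, with the authors' processed values at 0.0271 and with a stricter filter at 0.0497), and Kit at -0.29 ± 0.158 (adjusted p = 0.243). Fcgr3 lay at -0.18 with Itgb3-17 (adjusted p = 0.564) and at 1.04 with Itgb3-20 (0.00427), on opposite sides of the control except under median scaling (0.27 with Itgb3-17, and 1.22 with Itgb3-20, where the call was lost at 0.0554). Its difference between the hairpins was called (1.22, adjusted p = 0.0106) and was lost without Itgb3-17 replicate 2 at 1.18 and 0.0942 or replicate 3 at 1.17 and 0.0557, under median scaling and with no filter. Of 5 mast cell and basophil markers 1 rose and 0 fell, of 3 NK cell markers 1 and 0, of 3 megakaryocyte and platelet markers 0 and 1, and of 4 dendritic cell and antigen presentation markers 0 and 1, each the same adjusted over the list alone (2 and 0, 1 and 0, 0 and 1, and 0 and 1 at an unadjusted p under 0.05). The genes were Cpa3, a mast cell protease that was not above background in the controls (at least 1.42-fold higher, adjusted p = 0.00509), Prf1, the perforin of cytotoxic cells (0.98 ± 0.213, adjusted p = 0.00567; 0.0882 with no filter on dim probes), Thbs1, a platelet glycoprotein (-0.48 ± 0.139, adjusted p = 0.0273), and H2-DMa, an antigen loading chain (-0.70 ± 0.141, adjusted p = 0.00358). Neither fall was called under median scaling (adjusted p = 0.178 and 0.318). Thbs1 was lost without Luc control replicate 1 (-0.53, 0.0516), 2 (-0.50, 0.0647) or 3 (-0.44, 0.0825), without Itgb3-17 replicate 3 (-0.41, 0.072), without Itgb3-20 replicate 4 (-0.46, 0.0642) and with no background correction (0.0651).

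By limma 0 genes passed among 2 erythroid, 1 B cell, 4 T cell, 4 eosinophil and 4 stromal and endothelial markers. For the B cell marker Cd79b, selected but not otherwise described, the probe that stood for it was at 0.30 (adjusted p = 0.338). Another of its probes was called lower (-0.80, adjusted p = 0.00417). At an unadjusted p under 0.05 there were 0 of either direction in these lists except for 3 eosinophil markers on the lower side, of which 2 passed adjusted over the list alone. Cd8b1, a T cell coreceptor chain, was above background on all 8 arrays at 10.1 ± 0.225 in the controls (SD, n = 3), with a log2 difference of 0.16 ± 0.145 (adjusted p = 0.496). Nkg7, a granule protein of cytotoxic cells, was also above background on all 8 arrays (-0.16 ± 0.139, adjusted p = 0.49).

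**Figure D2:**
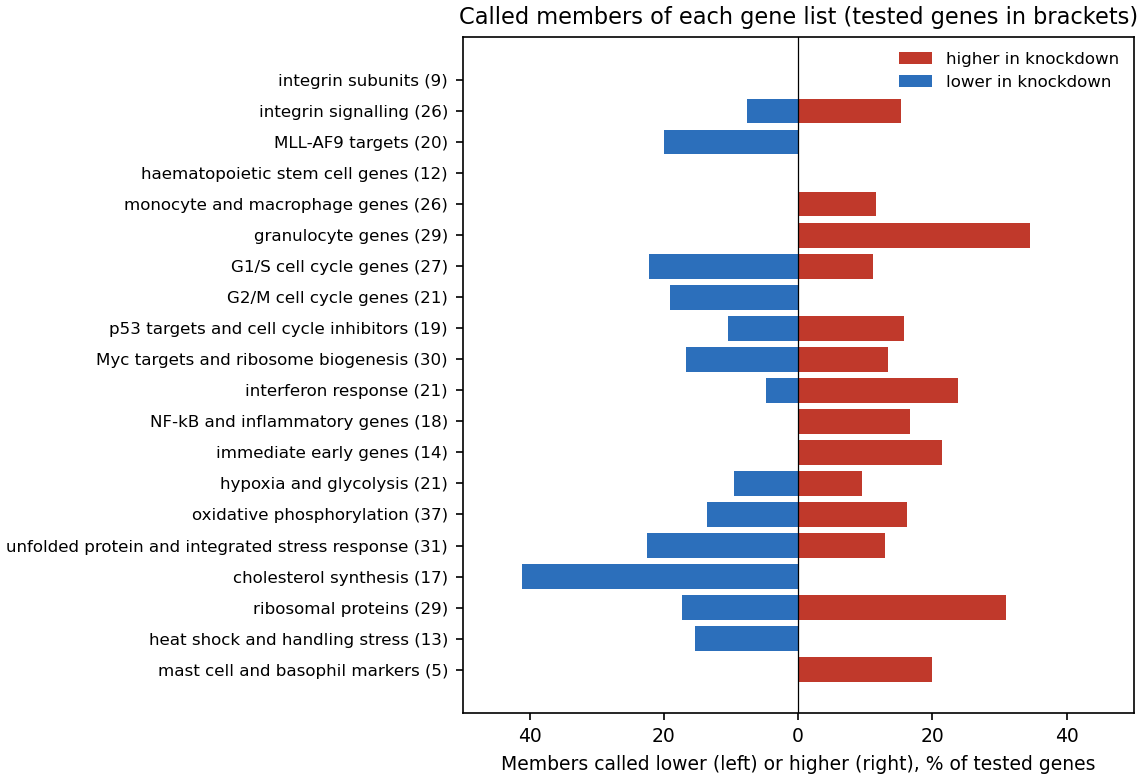
Share of the tested genes of each list called lower (left) or higher (right) in knockdown than in control, in percent of the tested genes given in brackets. Granulocyte genes have 10 of 29 called higher and cholesterol synthesis genes 7 of 17 called lower, while over all tested probes, calls on the lower side went from 1044 to 79 under median scaling.

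Each hairpin was also set against the controls alone. With Itgb3-17, the genes of largest change were Timm17a (-1.63), Erich5 (1.60), Eef2 (-1.59), Vkorc1, an enzyme of the vitamin K cycle (-1.57, adjusted p = 0.000751), and Kif1b, a kinesin motor (-1.56, adjusted p = 0.000393), of which Kif1b had another probe called in the opposite direction between knockdown and control. The other tested probes of Vkorc1 lay at 5.47 and 6.61 in the controls and at 5.37 and 6.62 with Itgb3-17. Neither was called between knockdown and control (0.06 and 0.26, limma adjusted p = 0.848 and 0.32). With Itgb3-20 the genes of largest change were Eef2 (-2.81), Hnrnpk, an RNA-binding protein (-2.05, adjusted p = 0.00374), Lyz1 (2.05), Rbbp7 (-2.02) and Hoxa5 (-2.02). Without Itgb3-20 replicate 4 Hnrnpk lost its call (-1.20, adjusted p = 0.0604) and Eef2 was at -1.72 (adjusted p = 0.0059). With no filter on dim probes Eef2 (adjusted p = 0.177 with Itgb3-17 and 0.0507 with Itgb3-20), Hnrnpk (0.0965) and Erich5 (0.0607) lost their calls. Eef2 and Hnrnpk were also lost with trend and robust moderation (0.157 with Itgb3-17 and 0.0528 with Itgb3-20 for Eef2, 0.0915 for Hnrnpk) and, for Eef2 with Itgb3-17 (0.0829) and Hnrnpk (0.0536), under median scaling. Granulocyte genes shifted up with Itgb3-20 (median 0.422, camera adjusted p = 8.22e-05) and MLL-AF9 targets shifted down (median -0.17, adjusted p = 0.00881), while cholesterol synthesis genes shifted down with Itgb3-17 (median -0.344, adjusted p = 0.0105). None of the 3 passed with the other hairpin: granulocyte genes (median 0.101) and MLL-AF9 targets (-0.0328) had an adjusted p of 0.575 with Itgb3-17, and cholesterol synthesis genes (-0.0881) of 0.196 with Itgb3-20. An estimated correlation was not run for these lists with each hairpin alone.

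Itgb3-17 gave 962 probes higher and 757 lower than control, and Itgb3-20 gave 760 higher and 702 lower. Under median scaling the counts were 1696 and 37 for Itgb3-17 and 167 and 42 for Itgb3-20, and with no filter on dim probes 593 and 447, and 401 and 331. The Itgb3-17 counts were 440 and 382 without its replicate 1, 422 and 334 without its replicate 2, 548 and 470 without Luc control replicate 2, and 627 higher without Luc control replicate 1. The Itgb3-20 counts were 130 and 184 without its replicate 4, where the remaining array is assumed to vary like the other groups, 457 and 463 without Luc control replicate 2, and 489 higher without Luc control replicate 1. They were 414 and 437 with array weights and 382 and 416 with only the Itgb3-20 and control arrays in the fit.

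Of the 88 called genes selected for knockdown against control, 54 were called with both hairpins, 14 with Itgb3-17 and not Itgb3-20, 14 with Itgb3-20 and not Itgb3-17, and 6 with neither, and the difference was called for 8. For 3 of the 88 the hairpins lay on opposite sides of the control. Of the 73 described, 54 were called with both hairpins. With Itgb3-17 and not Itgb3-20 these were Anln, Birc5, Fcgr2b, Mvd, Plk1, Ppan, Ppp1r15a, Rac1 and Uqcrc2, none with a called difference. With Itgb3-20 and not Itgb3-17 they were Bag3, Calr, Dusp6, Eya1, Hoxa9, Lyz2, Rbbp7, S100a9 and Umps. Thbs1 was called with neither.

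The hairpins changed many of the same genes. Called with both were 446 probes higher and 367 lower, among them Lyz1, Erich5, Hipk2 and Cyp51, and 2 were called in opposite directions. Independent lists of these sizes would share 54.9, 39.9 and 93.9, and unchanged groups simulated against the same controls shared 0.01 and 0.02 on average. The log2 fold changes of both hairpins correlated at 0.737 across probes, against 0.448 in the simulation, with a covariance of 0.111 against 0.016, a difference of 0.0953. The 3 controls were too few to be split with a pair or more on each side, so part of the excess may come from the shared controls. The overlap was 100 higher and 124 lower without Itgb3-20 replicate 4, 215 and 189 without Itgb3-17 replicate 2, 227 and 220 without Itgb3-17 replicate 1, 222 and 218 without Luc control replicate 2, 267 and 225 without Luc control replicate 1, 151 and 9 under median scaling and 232 and 179 with no filter.

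**Figure D3:**
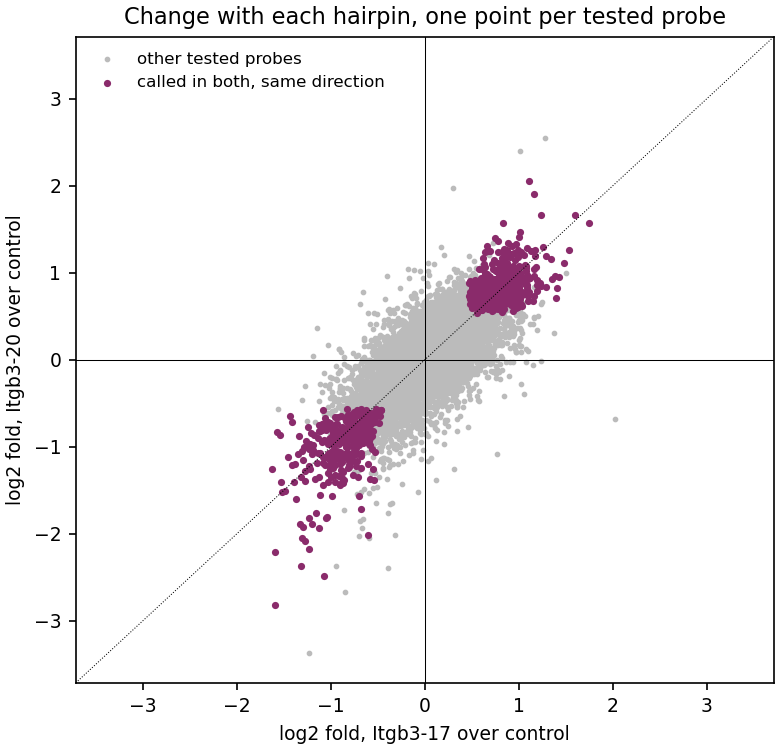
Log2 fold change over control with Itgb3-17 (horizontal) and Itgb3-20 (vertical), 1 point per tested probe, with the dotted line at equal change. Probes called with both hairpins in the same direction (446 higher, 367 lower) are coloured; the 3 control arrays are shared by both axes.

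The difference between the hairpins was tested directly. S100a9 was higher with Itgb3-20 than with Itgb3-17 by 1.67 ± 0.227 (SE; adjusted p = 0.00622), at 9.10 against 7.43, as were Prg2, a granule protein of eosinophils (1.51 ± 0.186, adjusted p = 0.00622), and Mapre2, a microtubule end-binding protein (1.44 ± 0.208, adjusted p = 0.00622). Hoxa5 was lower with Itgb3-20 (-1.41 ± 0.202, adjusted p = 0.00622), as was Gpd2, the mitochondrial glycerol phosphate dehydrogenase (-1.30 ± 0.279, adjusted p = 0.0485). Fcgr3, a receptor of the sort gate family, was higher with Itgb3-20 (1.22, adjusted p = 0.0106). Against control Mapre2 was at -0.66 with Itgb3-17 and 0.78 with Itgb3-20 (adjusted p = 0.0289 and 0.0249), Prg2 at -1.14 and 0.36 (0.00109 and 0.24), Gpd2 at 1.02 and -0.28 (0.0134 and 0.576), and Hoxa5 at -0.60 and -2.02 (0.0385 and 9.39e-05). The Itgb3-17 call of Mapre2 was lost without Luc control replicate 1 (-0.57) or 3 (-0.56) and Itgb3-17 replicate 1 (-0.59) or 2 (-0.64), with adjusted p from 0.0984 to 0.113. Its Itgb3-20 call was lost without Luc control replicate 2 (0.58, 0.096) or Itgb3-20 replicate 4 (0.59, 0.23), under median scaling (0.97, 0.0687), with no filter (0.118) and with only the groups compared (0.0627). The call of Hoxa5 with Itgb3-17 was lost without Luc control replicate 1 (-0.62), 2 (-0.57) or 3 (-0.61) and Itgb3-17 replicate 1 (-0.57) or 2 (-0.55), with adjusted p from 0.077 to 0.144. That of Gpd2 was lost without Luc control replicate 1 (0.95, 0.0528) or 2 (1.00, 0.0535) and Itgb3-17 replicate 2 (0.97, 0.0706). Gpd2 was called with Itgb3-20 without its replicate 4 (-0.97, 0.0311). Mapre2, Hoxa5 and Prg2 lost their Itgb3-17 calls under median scaling (adjusted p = 0.574, 0.764 and 0.095), and Mapre2, Hoxa5 and Gpd2 with no filter (0.126, 0.136 and 0.157). In all, 33 probes were higher and 38 lower with Itgb3-20 (limma; 1573 at an unadjusted p under 0.05). These counts were 12 and 6 without Itgb3-17 replicate 1, 2 and 0 without replicate 2 (531 and 645 unadjusted) and 10 and 8 without replicate 3, 18 and 60 without Itgb3-20 replicate 4, 68 and 162 without replicate 5, and 24 lower without Luc control replicate 2. They were 0 and 2 under median scaling (117 and 1083 unadjusted) and 0 and 1 with no filter (1911 and 1492 unadjusted), and in both settings each of the 6 named differences lost its call. Without Itgb3-17 replicate 2 the adjusted p was 0.0667 for Hoxa5 (-1.48), 0.0687 for Mapre2 (1.43) and 0.0942 for Fcgr3 (1.18), and Fcgr3 was at 1.17 (0.0557) without replicate 3. Gpd2 was lost without any array except Itgb3-20 replicate 4 (adjusted p from 0.0551 to 0.216, log2 difference from -1.34 to -0.62; -1.99 and 0.00158 without that array), and with a stricter filter (0.0589) or trend and robust moderation (0.0543). The counts rose to 121 and 109 with no background correction, 116 and 133 with the authors' processed values and 91 and 106 with trend and robust moderation.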

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

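The difference between the hairpins was a planned test; the tests that weigh explanations for it were chosen after the result was seen, and the late granulocyte genes were listed after some of their values had been seen.

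Itgb3-20 and Itgb3-17 target the same gene, yet the difference between them passed the test for 33 probes higher and 38 lower with Itgb3-20. These counts were 12 and 6, 2 and 0 (limma; 531 and 645 unadjusted) and 10 and 8 without Itgb3-17 replicates 1, 2 and 3, 18 and 60 without Itgb3-20 replicate 4, 68 and 162 without replicate 5, and 24 lower without Luc control replicate 2. They were 0 and 2 under median scaling (limma; 117 and 1083 unadjusted) and 0 and 1 with no filter (1911 and 1492 unadjusted). By gene the differences were 1.67 for S100a9, 1.51 for Prg2, 1.44 for Mapre2, -1.41 for Hoxa5 and -1.30 for Gpd2, and each of these 5 lost its call under median scaling (adjusted p from 0.0927 to 0.16) and with no filter (0.0532 to 0.307). Without Itgb3-17 replicate 2 Mapre2 (1.43, adjusted p = 0.0687) and Hoxa5 (-1.48, 0.0667) lost their calls, and Gpd2 lost its call without any array except Itgb3-20 replicate 4 (-1.34 to -0.62, 0.0551 to 0.216; -1.99 and 0.00158 without that array).

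Among the lists the camera test of the difference passed for granulocyte genes (median 0.195, adjusted p = 1.11e-05), MLL-AF9 targets (-0.181, 0.00608), monocyte and macrophage genes (0.172, 0.0139), mast cell and basophil markers (0.33, 0.00785), integrin signalling (0.188, 0.0149), hypoxia and glycolysis (0.174, 0.00848), p53 targets and cell cycle inhibitors (-0.138, 0.00785) and Myc targets and ribosome biogenesis (-0.0808, 0.0385). None of these 8 list calls held with an estimated correlation, where the adjusted p lay between 0.12 and 0.275.

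None of the 3 explanations tested for the hairpin difference was excluded. A stronger knockdown with Itgb3-20 cannot be told apart from effects of a hairpin on other genes: the Itgb3 probe was above background on 0 of 8 arrays, and when each Itgb3-17 array was held out, its own change from control opposed 10 of 18, 1 of 2 and 12 of 18 of the differences called without it (95% intervals 30.8% to 78.5%, 1.26% to 98.7% and 41% to 86.7%; 23 of 38 together), where a stronger knockdown needs fewer than an even share and the probes are not independent. A deviating array, Itgb3-20 replicate 4, at 26.6 on the principal component after the leading one where replicate 5 lay at 7.95, stays open: without it 78 probes were called, 30 of them among the 71, but replicate 5 then stood alone, with 1325 probes at an unadjusted p under 0.05 against 82 to 1120 for a single Luc control or Itgb3-17 array set against its own group in fits of fewer arrays. Mature granulocytes among the sorted cells stay open, although the c-kit and CD34 gate would remove them: the 7 tested late granulocyte genes other than S100a9 differed by a median of 0.58 (95% interval 0.177 to 0.855), with the abundant S100a8 at 10.9 with Itgb3-17 and 11.8 with Itgb3-20. The difference was called for S100a8 and Pglyrp1 (0.85 and 1.00, limma adjusted p = 0.031 and 0.0179). It was not called for Lcn2 (0.81), Cd177 (0.58), Camp (0.21), Ngp (0.18) and Ltf (0.03). All 7 are also in the granulocyte list, and 5 were above background on every control array.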

How the results depend on the processing

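Averaging the probes of a gene before the fit was chosen after seeing the data; the other settings were planned. Chip as a block was not run because the table headers name no chips, and the Itgb3 level got no value under the filter settings, which do not apply to it. Signal over background limited what was read, with Itgb3 above background on 0 of 8 arrays.

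Leaving out each array gave, for knockdown against control, 688 to 1380 probes higher and 679 to 1232 lower (688 and 679 without Luc control replicate 2, and 748 higher without Luc control replicate 1). Itgb3-17 gave 422 to 1190 and 334 to 983 (440 and 382 without its replicate 1, 422 and 334 without replicate 2, 627 higher without Luc control replicate 1, 548 and 470 without Luc control replicate 2). Itgb3-20 gave 130 to 865 and 184 to 870 (130 and 184 without its replicate 4, 489 higher without Luc control replicate 1, 457 and 463 without Luc control replicate 2). The hairpin difference gave 2 to 68 and 0 to 162: 12 and 6, 2 and 0 (limma; 531 and 645 unadjusted) and 10 and 8 without Itgb3-17 replicates 1, 2 and 3, 18 and 60 without Itgb3-20 replicate 4, 68 and 162 without replicate 5, and 24 lower without Luc control replicate 2. The overlap of the hairpins gave 100 to 481 higher and 124 to 483 lower, with correlations from 0.649 to 0.773 (100 and 124 without Itgb3-20 replicate 4, 227 and 220 without Itgb3-17 replicate 1, 215 and 189 without replicate 2, 267 and 225 without Luc control replicate 1, 222 and 218 without replicate 2). Lists called by camera were 0 to 1 higher and 0 to 2 lower, with 0 lower without Luc control replicate 3, 2 lower without Itgb3-17 replicate 2 or Itgb3-20 replicate 4, and 0 and 0 without Itgb3-20 replicate 5 (1 and 2 unadjusted). The Itgb3 difference stayed between -0.05 and -0.01. Some counts rose with an array left out (1380 and 1232 in knockdown without Itgb3-20 replicate 5), and the cause of these changes was not tested.

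Median scaling gave 79 probes lower in knockdown, 1696 and 37 with Itgb3-17, 167 and 42 with Itgb3-20, 0 and 2 in the difference (limma; 117 and 1083 unadjusted), an overlap of 151 and 9, and 2 lists higher; the cause was not tested. With no filter, which adds tests of dim probes, 649 were lower in knockdown, 593 and 447 changed with Itgb3-17, 401 and 331 with Itgb3-20, 0 and 1 in the difference (limma; 1911 and 1492 unadjusted), and the overlap was 232 and 179. The difference rose to 121 and 109 with no background correction, 116 and 133 with the authors' values, and 91 and 106 with trend and robust moderation, and Itgb3-20 gave 414 and 437 with array weights; the cause was not tested. With only the groups compared, Itgb3-20 gave 382 and 416 while Itgb3-17 rose to 1183 and 977; the cause was not tested. A 1.5-fold threshold, stricter by construction, left 715 higher. Averaged probes, with fewer features tested, gave 682 and 577 in knockdown, 541 and 457 with Itgb3-17 and 466 and 355 with Itgb3-20. Lists called were 0 higher in the fit of the knockdown arrays as a single group (camera; 1 unadjusted), 0 and 0 with an estimated correlation (0 and 2 unadjusted), 6 and 3 by fry, and 0 lower with the mean of all probes of a gene (2 unadjusted).

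The replicate numbers did not pair the arrays: same-numbered Luc control and Itgb3-17 arrays deviated from their group means with correlations of 0.0279, -0.024 and -0.00589, and not every array correlated best with its own number. With the replicate block, where only the Itgb3-17 arrays have a control of their number, 1256 probes were higher and 1050 lower, and 0 lists were higher by camera (1 unadjusted; granulocyte genes adjusted p = 0.535). Lyz2 went to -0.112 (adjusted p = 0.714) and Ccng1, selected but not described, to 0.0383 (0.91). This fit therefore compares Itgb3-17 alone with control. S100a9 (0.30), Eya1 (-0.37), Hoxa9 (-0.44), Dusp6 (0.35) and Thbs1 (-0.41) were not called in it (adjusted p = 0.261, 0.156, 0.0742, 0.167 and 0.0953), nor with Itgb3-17 without the block (0.366, 0.319, 0.284, 0.191 and 0.0917). Itgb7 (0.78) and Prg2 (-1.14) were called in both (0.00618 and 0.0256, and 3.73e-05 and 0.00109) and Xist (0.76) only with the block (0.00187 and 0.0894).

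For the 126 genes that the rule selected for knockdown against control, settings other than leaving out an array left 1001 results on their side of the threshold, ended 85 calls, added 27 and reversed 2, and leaving out an array left 892, ended 89 and added 7. Of these genes 88 were called, and 65 of the 88 stayed called without each array (33 of 46 rises and 32 of 42 falls). Of the 73 called genes described in the text, 9 lost their call without at least 1 array, against 14 of the 15 called genes selected but not described. The choice of which genes to describe shaped this contrast, so it does not show that those described are firmer. Under median scaling 22 of the 73 and 4 of the 15 lost their calls. Settings other than leaving out an array, and leaving out an array, ended 22 and 28 calls of the 10 hairpin differences followed by gene. Of the 29 single-hairpin changes they ended 21 and 16 and added 6 and 3, and of the lists they ended 5 and 3 and added 8 and 2.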

Other observations

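The tests of probe pairs in this part were chosen after the result was seen; the splits of the arrays were planned.

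Members of several housekeeping and stress lists were called in both directions between knockdown and control (limma), while none of the lists in this paragraph passed camera. Of 29 ribosomal protein genes 9 rose and 5 fell (12 and 6 adjusted over the list alone), among them Rpl32 at 0.98, Rpl23 at 0.86 (another of its probes was called in the opposite direction), Rpl30 at -1.34 and Rpl22 at -0.83. The list did not pass (camera adjusted p = 0.488) but did under median scaling (0.0291, with a shift of 0.416 relative to all tested probes). Of 37 oxidative phosphorylation genes 6 rose and 5 fell (6 and 6 adjusted over the list alone; camera adjusted p = 0.806), with Atp5o, an ATP synthase subunit, at 0.70 (another probe at -0.51, adjusted p = 0.0847) and Atp5pb, another, at -1.01, and with Uqcrc2 of complex III at -0.72 and Cox6a1 of the cytochrome oxidase at -0.73. Of 31 genes of the unfolded protein and integrated stress response 4 rose and 7 fell (5 and 8 adjusted over the list alone; camera adjusted p = 0.806). Its median was 0.0482, while its mean was -0.0512 and the test pointed down. Calr, a chaperone of the endoplasmic reticulum, fell by 1.30 (-0.66 with Itgb3-17, adjusted p = 0.0624, called without Itgb3-20 replicate 4 at -0.67 and 0.00873 or replicate 5 at -0.66 and 0.00733, and -1.93 with Itgb3-20, 0.000574) and Sdf2l1, a chaperone partner, by 0.95, while Atf4, the transcription factor of the integrated stress response, rose by 0.94 (another probe at -0.64, adjusted p = 0.0864) and its target Ppp1r15a by 0.71. Of 30 Myc targets and ribosome biogenesis genes 4 rose and 5 fell (6 and 5 adjusted over the list alone; camera adjusted p = 0.833), with Rrp12 at 1.12, Bop1 at 0.84, Ppan at 0.64 and Umps, an enzyme of pyrimidine synthesis, at -0.86 (adjusted p = 0.00843), which lost its call without Luc control replicate 1 (-0.68, adjusted p = 0.0576) and with no filter (0.1). Of 21 hypoxia and glycolysis genes 2 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.905), with Aldoa at 0.81 and Pfkp at -1.08, which lost its call with no filter (adjusted p = 0.104) and with trend and robust moderation (0.0535). Under median scaling the medians of the Myc and hypoxia lists turned from -0.0652 and -0.0679 to 0.223 and 0.177 (0.0737 and 0.0282 relative to all tested probes). Of the falls named in this paragraph those of Rpl30 and Calr were called in that setting.

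Of 21 interferon response genes 5 rose and 1 fell, the same adjusted over the list alone (median 0.208, camera adjusted p = 0.324; fry adjusted p = 0.00511, upward). Irgm1, an immunity GTPase, rose by 1.01, the transcription factor Irf1 by 0.73 and Oas1g by 0.69, while the immunoproteasome subunit Psmb8 fell by 1.05 and was lost under median scaling (adjusted p = 0.143) and with no filter (0.0662). Of 18 NF-kB and inflammatory genes 3 rose and 0 fell (4 and 1 adjusted over the list alone, 5 and 3 at an unadjusted p under 0.05; camera adjusted p = 0.488; fry adjusted p = 0.0302, upward), with the kinase Ikbke at 0.64. Of 14 immediate early genes 3 rose and 0 fell (4 and 0 adjusted over the list alone, and also 4 and 0 at an unadjusted p under 0.05; camera adjusted p = 0.488; fry adjusted p = 0.0302, upward), with the phosphatase Dusp6 at 0.61, lost without Luc control replicate 2 (0.56, adjusted p = 0.0566). Of 13 heat shock and handling stress genes 0 rose and 2 fell (2 and 2 adjusted over the list alone, 4 and 2 at an unadjusted p under 0.05; camera adjusted p = 0.806), with the chaperone regulator Bag3 at -0.64, lost without Luc control replicate 1 (-0.56, adjusted p = 0.0596), with no filter (0.052) and under median scaling (0.5). The mast cell and basophil list did not pass as a whole (camera adjusted p = 0.731). Of the Y-linked and X-inactivation genes only Xist was tested, at 0.56 ± 0.256 (SE, limma adjusted p = 0.154). With only this gene tested, adjusting over the list alone changes nothing, so Xist passed there at its unadjusted p only. It was called under median scaling (limma adjusted p = 0.0395). Without Itgb3-20 replicate 5, which left 1 array of that hairpin, it was at 0.90. Of its other tested probes 1 was called (0.52, adjusted p = 0.0189), and those at 0.27 and 0.05 were not (0.446 and 0.883).

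Probes of the same gene often disagreed between knockdown and control. Noise of dim probes is argued against as the whole cause, because log2 fold changes of the 305 pairs with both means above 7 correlated at only 0.15 (95% interval -0.00304 to 0.308), and 21 of the 63 such pairs with both probes called went in opposite directions. A probe-level difference between control and knockdown arrays, such as in labelling or hybridization, stays open: probes of a gene shared 26.1% of the variance beyond replicate error in knockdown against control and 54.8% in Itgb3-20 against Itgb3-17, a difference of -0.287 as a fraction (95% interval -0.361 to -0.219). A change in which transcript forms are made also stays open, since probes on the same transcript record correlated better than probes on different records by 0.119 (95% interval 0.0303 to 0.21), though 51 of 218 called pairs on the same record still went in opposite directions. Both may act, and the design holds no array that would separate them.

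Chance splits of the arrays were counted for the fits that compare at least 3 arrays a group. Fitting the 5 knockdown arrays against the 3 controls called 1883 probes, and 1 of the 56 splits of the arrays, the real one, gave as many. The highest other split gave 37, with the 3 Itgb3-17 arrays set against the rest. A chance assignment of these arrays is therefore unlikely, but 56 splits cannot exclude it. Every other split puts control and knockdown arrays together in a group, which widens the spread, so few calls were likely there. A difference between preparations, if arrays of a group shared one, is not excluded either. For Itgb3-17 against control the real split gave 2160 calls and the highest other 0 by limma (203 to 501 probes at an unadjusted p under 0.05 in the others), and the 10 splits are too few for a share under 0.05.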
